A study of Mus musculus with 6 samples.

How the data were processed

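Gene expression was measured by RNA sequencing of bone marrow cells sorted as LT-HSCs from mice on a control diet or on a high cholesterol diet for 3 months, with 3 libraries per group. Per the labels' protocols, RNA was extracted with a micro column kit and stranded libraries were made from mRNA. The submitters' processing notes name fastp, HISAT2 and StringTie and the builds GRCm38 and mm10, and versions, annotation and filters are not given in the sources used here. The deposited values are taken as FPKM, from the values themselves: the file headers give only a sample name and do not tell FPKM from RPKM. Each deposited table held 21878 rows. Of these, 27 rows carried a date in place of a gene symbol, held 0.127% of the FPKM and were left out, which left 21851 genes.

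Low values were whole multiples of what 1 read is worth, within a tolerance of 0.02 of a whole number, in 1766 of 2488 low genes (71.0%), and in 0% when wrong relative depths were put in. The size of 1 read gave a depth of 18820000 to 19980000 reads or fragments per library. Since the values are FPKM, no count model was used. Positions are from GENCODE vM21 on GRCm38, and a transcript length was found for 97.0% of the tested genes.

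The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust empirical Bayes on log2(FPKM + 1), two-sided and without a covariate. It took genes with at least 1 FPKM in at least 3 libraries, with Benjamini-Hochberg adjustment of p and a threshold of 0.05. The 40 gene lists were fixed before the data were examined, as were the test, the alternatives tried and the rule for named genes. Of the lists, 39 had tested members, and camera compared each with all other genes using a preset correlation of 0.01, with an estimated correlation and fry beside it. With an estimated correlation 5 of the 18 calls held. They were those of HSC aging, myeloid progenitors, megakaryocyte and platelet genes, basophils with mast cells and eosinophils, and DNA replication. With an estimated correlation and the replicate block together 0 held. The block leaves that test few degrees of freedom, so this loss says little about any single list. Without the block the test with an estimated correlation has few as well. Some calls were lost although the estimated correlation was at or below the preset 0.01. They were those of MHC class II (-0.001), autophagy and lysosome (-0.01), cholesterol synthesis (0.001), lymphoid priming (-0.009) and unfolded protein genes (-0.019). Correlation between genes does not explain those losses. For ribosomal proteins it was 0.944. With the block and the preset correlation all 18 calls held. The median, mean and camera direction differed in sign for glycolysis, erythroid and sex-linked lists, none of which was called. The named genes are the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group reached 1 FPKM, leaving out gene models and pseudogenes. Up to 4 members with the smallest p in each list were named too, as were the sex-linked and sort marker genes. Some genes that this rule takes are not reported here. Genes and lists named after their values were seen are marked as such.

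Replicates were compared first. Between CD libraries, and between HCD replicates 1 and 3, the median squared difference over genes with 100 to 1000 reads was 2.31 to 2.77 times that of sampling. It was 6.35 and 7.17 for HCD replicate 2 with the other HCD libraries and 5.82 to 10.05 between groups. These ratios take each read as independent. If reads were counted in pairs of mates, as in the simulation below, sampling noise would be larger and the ratios lower. The values therefore do not show whether the libraries are separate animals or technical replicates, and each library was counted once. The replicate numbers were checked for pairing by the correlation of deviations from the group means across genes. It was 0.103, 0.292 and 0.166 for the same-numbered pairs, all above the bound of 0.1 set beforehand. The alternative fit with a block, planned before this check, treats the numbers as possible pairs. The labels do not say that they pair. The main test stayed unpaired. For different-numbered pairs it was -0.25 to 0.098. The highest were CD replicate 1 with HCD replicate 3 (0.098) and CD replicate 3 with HCD replicate 1 (0.094), close to the 0.103 of pair 1, so the values hardly tell pair 1 from these. The deviations within a group cancel, so these correlations are not independent. Replicate 2 minus replicates 1 and 3 also fell with transcript length in both groups (Spearman rho -0.13 in CD and -0.27 in HCD). Such a shared trend could give the same correlations, so pairing is not settled.

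The test was also run on 6 simulated sets of 10337 to 10352 genes with 200 changed genes in each. It recovered 33.7% of genes changed 1.25-fold, 87% of those changed 1.5-fold, 99.7% at 2-fold and 100% at 4-fold. Of the calls 8.2% were false, above the nominal share, and 0 recovered genes had the wrong sign. The simulated libraries all had 1 common spread, without a library apart like HCD replicate 2, and the changed genes averaged at least 2 FPKM. These shares therefore need not hold for the real data. Alternatives were another pseudocount, no filter and a stricter filter, quantile normalization, TMM factors computed on the values, the replicate number as a block, each library left out in turn and a threshold of 0.1. Added after seeing the data were the removal of the trend against transcript length, with and without the block, and the averaging of HCD replicates 1 and 3. The count-based alternatives were not run, because the values are FPKM. Figures were drawn with matplotlib 3.10.9 and tables were prepared with python 3.11.15, numpy 2.4.6 and pandas 2.3.3.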

Results

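RNA from bone marrow cells of wild-type mice sorted as long-term haematopoietic stem cells (LT-HSCs, the cells that sustain blood formation) was sequenced after 3 months on a control diet (CD, 3 libraries) or a high cholesterol diet (HCD, 3 libraries). The deposited values are FPKM per gene, with sums from 427219 to 462370 per library. From the size of 1 read in the low values, the depth was estimated at 18820000 to 19980000 reads or fragments per library. At this depth 1 FPKM corresponds to about 59 reads for a transcript of the median length of 3076 bp. Between 10549 and 10675 genes reached 1 FPKM in each library. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

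The first principal component held 54.2% of the variance and parted the diets. The second held 26.5% and set HCD replicate 2 at -14.66, against 7.81 and 10.11 for HCD replicates 1 and 3.

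**Figure D1:**
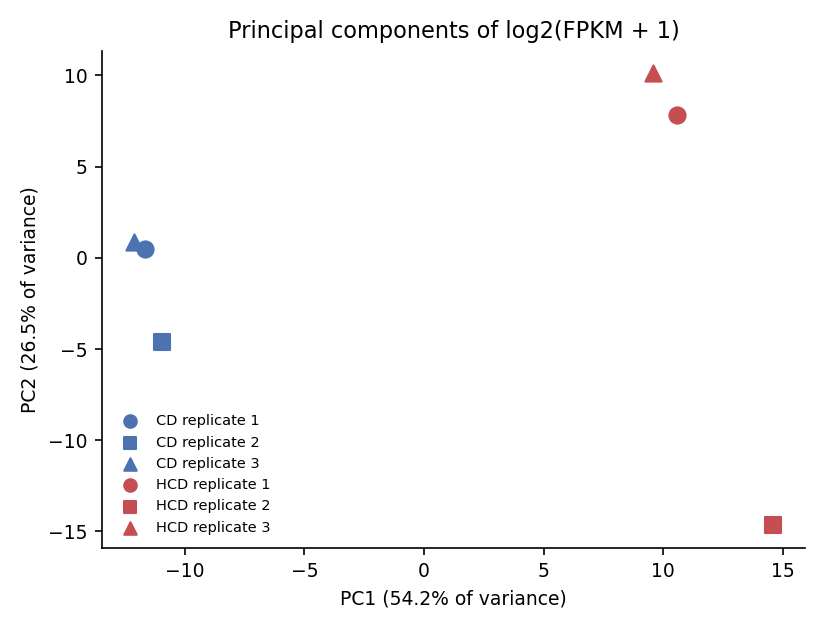
First and second principal components of log2(FPKM + 1) over the tested genes, 1 point per library, coloured by diet and shaped by replicate number. The CD libraries lie between -12.11 and -10.95 on the first component and the HCD libraries between 9.56 and 14.58, and HCD replicate 2 lies apart from the other HCD libraries on the second.

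The comparison of HCD with CD asks which transcripts differ in these cells after the cholesterol-rich diet. Under HCD, the zinc finger transcription factor gene Klf2 was 6.99-fold higher, at 317 ± 52.5 FPKM (SD, n = 3) against 45.4 ± 5.52 under CD (chromosome 8, 72319033 to 72321656, GRCm38; limma adjusted p = 1.17e-05). Within HCD, Klf2 was lowest in replicate 2 (256 FPKM, against 350 and 345), as was the list of immediate early genes described below. For these genes handling of the cells cannot be told apart from diet in this design. Elane, which encodes neutrophil elastase (chromosome 10, 79886247 to 79888215), was 4.02-fold higher, at 180 ± 4.74 against 44.8 ± 1.14 FPKM (adjusted p = 1.61e-07). The chromatin protein gene Hmga2 (chromosome 10, 120361275 to 120476469) fell from 4.88 ± 0.30 to 1.01 ± 0.32 FPKM (adjusted p = 0.000363). The HSP110 chaperone gene Hsph1 (chromosome 5, 149614287 to 149636376) fell from 49.2 ± 0.60 to 16.5 ± 0.60 FPKM (adjusted p = 2.05e-06). Among the gene lists, 14 of 23 genes of granulocyte and monocyte progenitors and 15 of 22 that rise with the age of HSCs were higher under HCD, and 12 of 26 DNA replication genes were lower. These 3 list calls held with an estimated correlation between genes (adjusted p = 0.0496, 0.03 and 0.0496), but not once the replicate block was added to it (adjusted p = 0.193 in each). The test with an estimated correlation has few degrees of freedom, and fewer with the block, here and for the lists below. With the preset correlation the block ended no list call.

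The other rises among the 12 largest were those of the transcription factor genes Atf3, Klf4, Klf6 and Fosb, the protease inhibitor gene Slpi, and Hp, Ms4a3, Ly6c2, S100a8 and Clca3a1. Within HCD these transcription factor genes were lowest in replicate 2, as Klf2 was. Slpi went from 6.36 ± 1.07 to 40.2 ± 2.44 FPKM, Klf6 from 77.6 ± 5.16 to 307 ± 58.3. Ms4a3, a gene of granulocyte and monocyte progenitors, went from 9.64 ± 0.76 to 39.9 ± 4.82 FPKM. The other falls among the 12 largest were those of Igll1, Slc35d3, Mid1, Itgb5, Wfdc18, C1qa, Ccnd1, C1qb, Shisa8 and Mdn1. Ccnd1, which encodes cyclin D1, fell from 14.7 ± 1.49 to 7.51 ± 1.14 FPKM, and Igll1, a surrogate light chain gene of early B cells, from 2.57 ± 0.42 to 0.49 ± 0.41. Across the 10676 genes tested, limma trend on log2(FPKM + 1) placed 1488 past an adjusted p of 0.05, 670 higher and 818 lower under HCD. With TMM factors the split was 785 higher and 597 lower, and with the trend against transcript length removed it was 759 and 574, the latter chosen after seeing the data. Longer transcripts were lower under HCD, with a Spearman rho of -0.26 between length and log2 change (-0.16 without HCD replicate 2). Within HCD, replicate 2 minus the mean of the others had a rho of -0.27 with length. Of the 1488 genes, 45 rose and 5 fell more than 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. With a pseudocount of 0.1 in place of 1, 98 genes passed both bounds, against 50. The groups did not overlap in 4026 of the tested genes (37.7%), where chance gives 10%. The count of genes past the threshold went from 435 without CD replicate 1 to 2672 without HCD replicate 2, and was 927 when HCD replicates 1 and 3 were averaged into 1 sample.

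**Figure D2:**
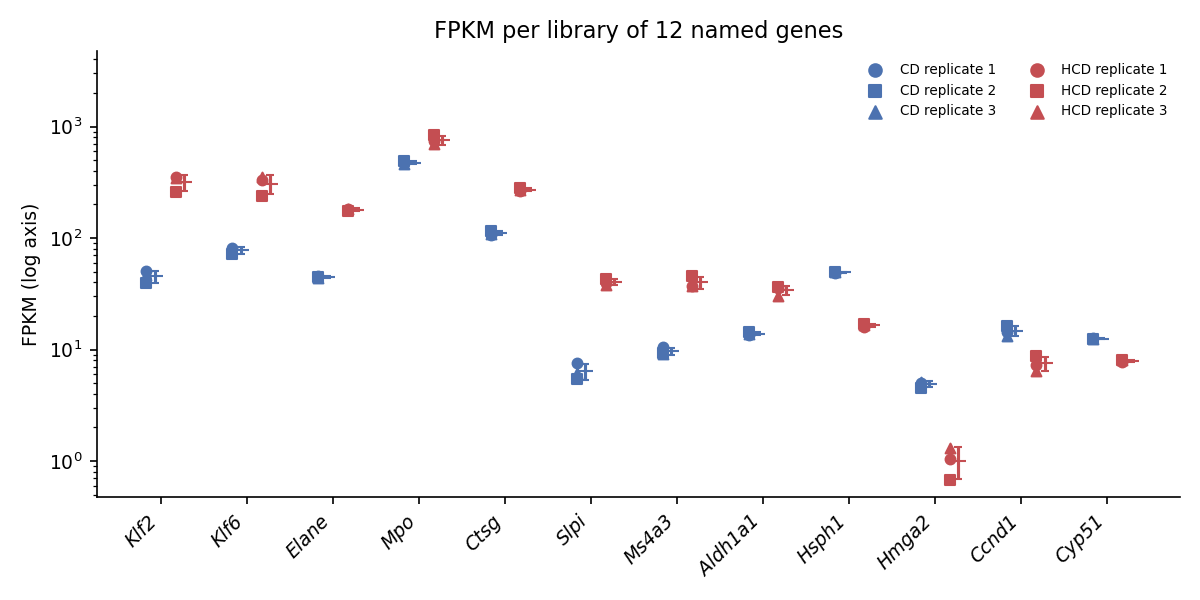
FPKM of 12 genes named in the text (log axis), 1 point per library, with the mean and SD of the 3 libraries of each diet beside the points. Klf2 rose from 45.4 to 317 FPKM and Hsph1 fell from 49.2 to 16.5.

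Among the myeloid progenitor genes, 14 of 23 tested members rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 0.38 (camera adjusted p = 2.70e-13, and adjusted p = 0.0496 with an estimated correlation, but adjusted p = 0.193 once the replicate block is added). Ctsg, the cathepsin G gene, went from 111 ± 4.03 to 271 ± 7.21 FPKM, and Ly6c2 from 9.63 ± 0.63 to 39.4 ± 3.44. Mpo (myeloperoxidase) rose from 475 ± 12.04 to 758 ± 71.8 FPKM and Prtn3 (proteinase 3) from 238 ± 6.67 to 426 ± 11.8, both named after their values were seen. The faller was Csf3r, from 42.7 ± 4.22 to 33.3 ± 3.95 FPKM. Of the list's transcription factor genes, Cebpa, Cebpb, Gfi1, Irf8 and Spi1 did not pass, and Cebpe rose from 0.98 ± 0.56 to 3.29 ± 0.64. These too were named after their values were seen. Of the 9 tested genes of mature neutrophils, from 20 listed, 8 rose and 1 fell, with a median log2 change of 1.37 (adjusted p = 1.06e-08, but adjusted p = 0.0514 with an estimated correlation). Lcn2, Wfdc21, Camp and Retnlg averaged 0.29, 0.08, 0.44 and 0.64 FPKM in CD and passed the filter only through the HCD libraries. The count and the median therefore lean towards rises. Their levels were low: S100a9 went from 4.80 ± 0.72 to 14.02 ± 2.08 FPKM and Ngp from 1.05 ± 0.15 to 3.68 ± 0.57. Of the 9 tested genes of basophils, mast cells and eosinophils, 6 rose and 0 fell (adjusted p = 2.24e-06, and adjusted p = 0.0496 with an estimated correlation, but adjusted p = 0.193 once the replicate block is added). Fcer1a, which encodes a chain of the IgE receptor, went from 1.88 ± 0.57 to 6.67 ± 0.65 FPKM, and Cpa3, a mast cell carboxypeptidase gene, from 18.2 ± 1.95 to 28.8 ± 2.54.

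Of 22 tested genes known to rise in HSCs of old mice, 15 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 0.53 (camera adjusted p = 2.32e-15, and adjusted p = 0.03 with an estimated correlation, but adjusted p = 0.193 once the replicate block is added). Aldh1a1, a retinaldehyde dehydrogenase gene, went from 13.9 ± 0.46 to 34.1 ± 3.19 FPKM. Selp (P-selectin) went from 9.61 ± 0.50 to 17.5 ± 1.01 and the metallothionein gene Mt1 from 4.89 ± 0.49 to 12.1 ± 0.85. The megakaryocyte and platelet list had 9 risers and 1 faller of 18 tested (adjusted p = 2.16e-08, and adjusted p = 0.0496 with an estimated correlation, but adjusted p = 0.193 once the replicate block is added). Among them Itga2b (CD41) went from 36.1 ± 1.60 to 62.2 ± 4.30 FPKM. This list shares Selp, Slamf1, Vwf, Sdpr and Itgb3 with the HSC aging list, and the risers Selp, Slamf1 and Vwf count in both. The HSC identity genes went both ways, with 4 of 24 higher and 4 lower and no call for the list (adjusted p = 0.432). Gata2 rose from 47.7 ± 0.21 to 63.7 ± 6.99 FPKM and Slamf1 (CD150) from 1.79 ± 0.47 to 3.41 ± 0.27. Txnip fell from 175 ± 0.27 to 133 ± 0.82.

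Immediate early genes, which respond within minutes to stimulation and also to cell isolation, had 15 risers and 4 fallers of 24 (adjusted p = 4.35e-09, but adjusted p = 0.352 with an estimated correlation). Fos went from 661 ± 19.5 to 1695 ± 89.5 FPKM, Dusp1 from 221 ± 2.95 to 511 ± 4.25 and Btg2 from 40.2 ± 1.09 to 111 ± 15.7. The list's mean log2 difference from CD was 0.772, 0.375 and 0.787 in HCD replicates 1, 2 and 3. The quiescence list, which shares Btg2, Egr1 and Nr4a1 with it, had 10 risers and 3 fallers of 26 (adjusted p = 5.89e-05, but adjusted p = 0.352 with an estimated correlation), with means of 0.590, 0.281 and 0.601 in the same libraries.

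Genes of cholesterol synthesis and uptake had 0 risers and 8 fallers among 25 tested (10 fell adjusted over the list alone), with a median log2 change of -0.18 (camera adjusted p = 0.000263, but adjusted p = 0.0541 with an estimated correlation). The estimated correlation was 0.001, below the preset 0.01, so correlation between these genes does not explain that loss. Cyp51, a lanosterol demethylase gene (chromosome 5, 4081145 to 4104746), fell from 12.5 ± 0.15 to 7.92 ± 0.19 FPKM. Sqle (squalene epoxidase) fell from 20.1 ± 1.43 to 13.3 ± 0.44. In the cholesterol efflux list 3 of 18 rose and 0 fell (adjusted p = 0.000123, but adjusted p = 0.0779 with an estimated correlation). They were Tspo, Mylip, which encodes a ligase that degrades the LDL receptor, and Apoe, at 106 ± 4.08 against 137 ± 16.9 FPKM. In fatty acid metabolism 2 of 20 rose and 3 fell and camera did not call the list (adjusted p = 0.518). Cpt1a, the gene for the carnitine transferase of mitochondrial fatty acid import, rose from 40.0 ± 0.88 to 57.2 ± 0.21 FPKM. Fasn (fatty acid synthase) fell from 34.3 ± 0.01 to 24.2 ± 1.32. Neither ferroptosis list was called. Of 19 drivers 1 rose, Cybb (adjusted p = 0.223 for the list). Of 22 defence genes Mt1 rose and Hmox1 (haem oxygenase) fell from 5.69 ± 0.24 to 2.93 ± 0.03 FPKM (adjusted p = 0.782).

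DNA replication genes had 0 risers and 12 fallers of 26, with a median log2 change of -0.20 (camera adjusted p = 5.28e-06, and adjusted p = 0.0496 with an estimated correlation, but adjusted p = 0.193 once the replicate block is added). Mcm6, a subunit of the replicative helicase, fell from 165 ± 1.48 to 137 ± 6.39 FPKM and Uhrf1 from 78.8 ± 1.32 to 63.2 ± 4.08. In the G2 and M list 0 rose and 5 of 26 fell, without a call for the list (adjusted p = 0.112). Lymphoid priming genes had 0 risers and 6 fallers of 17 (adjusted p = 0.000673, but adjusted p = 0.0653 with an estimated correlation and 0.0545 with a filter of 5 FPKM). The recombinase gene Rag2 fell from 2.28 ± 0.15 to 1.03 ± 0.10 FPKM, and Notch1, from 23.6 ± 0.98 to 17.9 ± 2.07. Of 32 interferon-stimulated genes 1 rose and 8 fell (adjusted p = 0.012, but adjusted p = 0.193 with an estimated correlation). Usp18 fell from 9.48 ± 1.05 to 5.69 ± 0.36 FPKM, and Ifitm1 rose from 274 ± 8.34 to 362 ± 16.4. The unfolded protein list had 1 riser and 9 fallers of 24 (adjusted p = 0.0433, but adjusted p = 0.193 with an estimated correlation and 0.067 with TMM factors). Hsp90b1 fell from 240 ± 0.71 to 178 ± 4.08 FPKM. Autophagy and lysosome genes had 7 risers and 0 fallers of 27 (adjusted p = 0.000123, but adjusted p = 0.0514 with an estimated correlation). Sqstm1 went from 67.5 ± 1.40 to 82.9 ± 2.65 FPKM. The niche and adhesion list had 6 risers and 3 fallers of 19 (adjusted p = 0.019, but adjusted p = 0.576 with an estimated correlation), with mean log2 differences of 0.189, 0.007 and 0.196 in HCD replicates 1, 2 and 3. Of 44 ribosomal protein genes none passed by limma (0 higher, 0 lower), although camera called the list higher (adjusted p = 1.23e-08, but adjusted p = 0.576 with an estimated correlation and 0.865 after quantile normalization). HCD replicate 2 carried most of that rise, with a mean log2 difference from CD of 0.296, against 0.089 and 0.048 in HCD replicates 1 and 3.

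**Figure D3:**
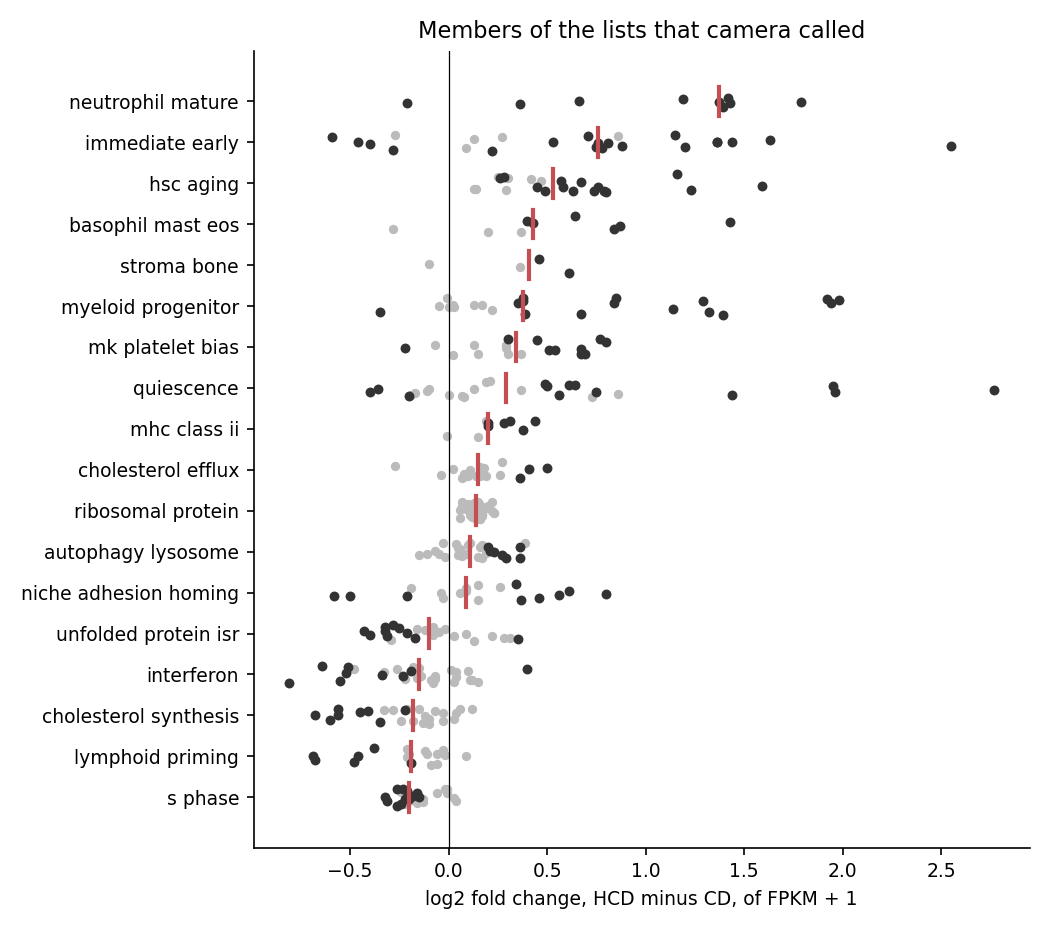
Log2 fold change of FPKM + 1, HCD minus CD, for the members of the 18 lists that camera called with the preset correlation. Each point is a gene, black where it passed the threshold over all genes and grey where it did not, and the red bar is the median of the list, from -0.20 for DNA replication to 1.37 for mature neutrophils.

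Among the lists of other cell types, MHC class II genes had 6 risers and 0 fallers of 9 (adjusted p = 2.24e-05, but adjusted p = 0.0514 with an estimated correlation). H2-Ab1 went from 65.4 ± 1.99 to 85.3 ± 7.14 FPKM. The stroma and bone list had 2 risers, Pdgfrb and Sparc, of 4 tested from 20 listed (adjusted p = 0.0197, but adjusted p = 0.352 with an estimated correlation, and without a call when any HCD library was left out). Sparc was near the filter, at 0.42 ± 0.16 FPKM under CD and 1.15 ± 0.09 under HCD. Camera did not call the lists of monocytes and macrophages (2 of 10 higher, 3 lower, adjusted p = 0.818), or B cells (1 of 6 higher, 1 lower, adjusted p = 0.409). Nor did it call those of T and NK cells (2 of 4 higher, 1 lower, adjusted p = 0.141), dendritic cells (0 of 7 higher, 2 lower, adjusted p = 0.137), endothelium (2 of 8 higher, 2 lower, adjusted p = 0.776) or erythroid cells (0 of 8 higher, 1 lower, adjusted p = 0.848). Within them, the macrophage complement genes C1qa and C1qb fell, and Jchain, the immunoglobulin joining chain gene, rose from 40.3 ± 2.82 to 108 ± 8.68 FPKM. The remaining lists without a call were NF-kB and inflammation (4 of 24 higher, 0 lower), oxidative phosphorylation (1 of 34 higher, 0 lower), antioxidant genes (1 higher and 1 lower of 27), and iron and haem (0 higher and 1 lower of 20). Also without a call were apoptosis (2 higher and 0 lower of 18), TGF-beta and BMP (2 higher and 2 lower of 20), p53 and DNA damage (4 higher and 4 lower of 23) and glycolysis and hypoxia (3 higher and 2 lower of 26).

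The gate named by the submitters takes cells without lineage markers that carry KIT and SCA1 and lack CD34 and CD135 on their surface. The transcripts of these sort markers did not pass the test between diets as single genes. As a list they were called lower under HCD by fry (adjusted p = 0.00795) and not by camera (adjusted p = 0.279). Kit averaged 120 FPKM over the 6 libraries and Ly6a (SCA1) 64.2. Cd34, however, averaged 464 ± 16.0 FPKM (SD over 6 libraries), above 98.9% of tested genes, and Flt3 (CD135) 109 ± 5.73. Slamf1 averaged 2.60 and Vwf 3.35 FPKM, while Cd48, a marker of multipotent progenitors, averaged 70.2. The libraries are therefore called here the libraries labelled LT-HSC. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were expressed in all 6 libraries and none passed the test between diets by limma.

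**Figure D4:**
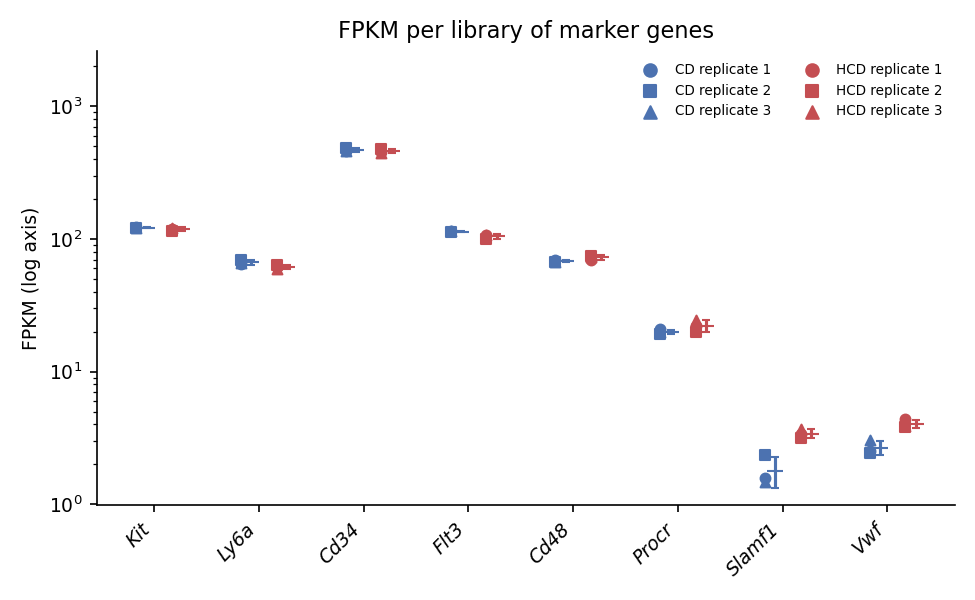
FPKM of 4 sort marker genes (Kit, Ly6a, Cd34 and Flt3) and 4 other marker genes of HSCs and progenitors (log axis), 1 point per library, with mean and SD of the 3 libraries of each diet. Cd34 and Flt3 averaged 464 and 109 FPKM over the 6 libraries, and Slamf1 averaged 2.60.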

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

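The alternatives that remove the trend against transcript length, and the averaging of HCD replicates 1 and 3, were chosen after seeing the data. The number of genes past the threshold was within 1.5 times of 1488 with a pseudocount of 0.1 (1466), no filter (1149), a filter of 5 FPKM (1282), quantile normalization (1650), TMM factors (1382) and the length trend removed (1333). With the replicate block it was 1873, and the paired fit ended no call of a list with the preset correlation or of a named gene. With both the block and an estimated correlation 0 of the 18 lists were called, and the 5 that hold without the block had an adjusted p of 0.193 each. Among list members not named, it ended those of H2-Eb1 and Bcl11a. The count fell to 435 without CD replicate 1, 551 without CD replicate 2, 509 without CD replicate 3 and 688 without HCD replicate 1, was 1081 without HCD replicate 3, and rose to 2672 without HCD replicate 2. Over these the genes higher went from 258 to 1171 and those lower from 177 to 1501. Fewer samples are 1 part of these falls, and HCD replicate 2 adds spread within its group. With HCD replicates 1 and 3 averaged, 927 genes passed, 445 higher and 482 lower. At an adjusted p under 0.1, 2419 passed, 1011 higher and 1408 lower. Of 18 lists called, 5 held with an estimated correlation, and of the 4 of other cell types 1 did. Some of the lists lost had an estimated correlation no higher than the preset 0.01, such as cholesterol synthesis (0.001). Fry, which does not compare a list with other genes, called 7 of all 10 lists of other cell types, among them 3 that camera did not call. The stroma and bone call also ended in 5 other settings and that of the unfolded protein list in 4. The cause of other changes was not tested.

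Directions turned only where nothing was called. For the ferroptosis defence list camera turned to lower although the mean log2 change stayed above 0, at 0.006 after quantile normalization and 0.007 with the length trend removed, with or without the replicate block. Fry gave the direction opposite to camera's for 7 lists, those of ferroptosis defence (mean 0.004), HSC identity (mean 0.034), TGF-beta and BMP, antioxidant genes, glycolysis and hypoxia, erythroid cells and sex-linked genes, and called none of them. Among single genes, with the length trend removed, with or without the replicate block, Tcf4 was at 0.013, Kdm5d at 0.011, Uty at 0.010 and Kit at 0.025. Leaving out 1 library at a time, the gene Uty ranged from -0.104 to 0.008 (the latter without CD replicate 3). The gene Eif2s3y ranged from -0.096 without HCD replicate 3 to 0.16 without HCD replicate 2, with -0.013 without CD replicate 2 and -0.015 without HCD replicate 1. It was at -0.056 with HCD replicates 1 and 3 averaged. The gene Hspa1a ranged from -0.015 without HCD replicate 3 to 0.296 without HCD replicate 2, and was at -0.007 with HCD replicates 1 and 3 averaged. Over the named genes and all alternatives, 2358 values kept their direction and side of the threshold, 189 lost the threshold and 61 gained it. At about 59 reads per FPKM, genes near 1 FPKM have the widest counting error.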

Other observations

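The lists in this paragraph were written after some of their members had been seen to change, so they describe these libraries and test nothing. Of 51 tested ribosome assembly factors, 34 fell under HCD and 0 rose, with a median log2 change of -0.30. Noc2l went from 123 ± 1.46 to 96.4 ± 2.63 FPKM (SD, n = 3) and the nucleolar helicase gene Ddx21 from 98.0 ± 0.86 to 79.6 ± 1.41. With the trend against transcript length removed 27 fell. Of 43 tested chaperone and heat shock genes, 24 fell and 1 rose, with a median of -0.26. Dnaja1 went from 101 ± 1.03 to 69.9 ± 1.28 FPKM and Hspd1 (HSP60) from 244 ± 5.71 to 173 ± 5.86. Both cold-inducible RNA-binding protein genes rose, Rbm3 from 80.0 ± 1.07 to 133 ± 5.25 FPKM and Cirbp from 44.3 ± 3.05 to 70.1 ± 3.49. Of 13 tested clock genes 1 fell, Per2, and 0 rose.

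The tests below were chosen after the results were seen, except the count of splits. Transcripts of Cd34 and Flt3 were abundant in all 6 libraries labelled LT-HSC, although the gate excludes cells with these proteins on their surface. Neither test run on this decides its origin. The highest Flt3 value was 1.15 times the lowest, so no library stands apart, but a mislabelled or poor sort shared by all 6 would leave the same. Of the 19 lymphoid-primed genes other than Flt3 that were found, 16 averaged at least 1 FPKM, but these are the members that pass the filter, so the count does not show whether CD34+ CD135+ progenitors were among the sorted cells. Transcript and surface protein may also part in these cells, and this was not tested.

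Of 23 tested granulocyte and monocyte progenitor genes 14 were higher under HCD and 1 lower, and the call of the list was lost with an estimated correlation and the replicate block together (adjusted p = 0.193). Neutrophils late in maturation would bring more of their own abundant transcripts than of progenitor proteases. Yet the summed rise of the neutrophil list, 49.4 FPKM, was 0.064 of the 767 FPKM by which Mpo, Elane, Ctsg and Prtn3 rose. This argues against such late neutrophils only as the source of the progenitor genes, and earlier stages were not tested. The neutrophil list itself rose in 8 of 9 tested members, with a median log2 change of 1.37, and the origin of that rise stays open. Some of these members passed the filter only through the HCD libraries, so that count and median lean towards rises. For a lower share of the main cell type the values point both ways. The lymphoid-primed list was lower in every HCD library, at most -0.22 on the log2 scale, where the myeloid list was 0.63 to 0.69 higher. With Flt3 at 109 and Dntt at 301 FPKM the lymphoid-primed genes may belong to the main type, whose genes a lower share would lower. Of the sort markers, Cd34 and Kit moved by only -0.04 each, but Flt3 moved by -0.12 and Ly6a by -0.11. Fry called the sort marker list lower (adjusted p = 0.00795), and camera did not (adjusted p = 0.279). Against a lower share, lists of other cell types parted in every HCD library. Neutrophils were at 0.975 to 1.16, monocytes and macrophages at -0.238 to -0.162 and dendritic cells at -0.156 to -0.106. This does not exclude it: other progenitors carry Cd34 and Kit too, and the macrophage genes that fell (such as C1qa and C1qb) lie near 1 FPKM. Ccr2 and Cd68 of the monocyte and macrophage list rose. Its summed FPKM was higher in every HCD library, at 207.4 to 245.5 against 192.7 to 202.8 in CD. Most of that sum was Lyz2, at 171 FPKM under HCD against 146 under CD. Lyz2 did not pass by limma (adjusted p = 0.0819) and is also in the myeloid progenitor list, so the sum adds little on monocytes and macrophages. The dendritic list holds Flt3, so a lower share stays open. More granulocyte-monocyte progenitors in the sorted cells cannot be told apart from a change within the cells labelled LT-HSC. The HSC identity list moved by -0.02 to 0.07, which a small share of progenitors would also leave. These progenitors lack SCA1 and carry CD34, so the stated gate would remove them, and they could be a source only if the gate let some through, as the abundant Cd34 transcripts leave possible. A response of the cells to the diet stays open.

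Of 24 tested immediate early genes 15 were higher under HCD and 4 lower, a list call that was lost with an estimated correlation (adjusted p = 0.352), and 3 explanations of these rises stay open. For 1 dissociation response that raises the whole fixed list, 2 of its 5 heat shock members fell (Hspa8 and Hsp90aa1) and 1 rose (Dnajb1), short of the 3 falls that would have counted against it (the median of -0.26 of the later chaperone list is not used as a test, since that list was written because such genes had fallen). If the same change had raised the immediate early and the myeloid genes, HCD replicate 2 would keep a like share of both rises, but its median log2 rise was 0.65 times that of HCD replicates 1 and 3 for the former and 1.34 times for the latter, a difference of -0.69 that rests on 1 library. Handling time or processing day may differ between the diets and cannot be told apart from diet in this design, and within HCD the highest median rise on the linear scale was 1.28 times the lowest. No biological explanation was tested here, and the diet stays among the open ones.

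The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1488 genes past the threshold by limma, and it was the only 1 with as many; the highest of the others was 0. The 3 others that part every same-numbered pair also gave 0, with 89 to 203 genes at an unadjusted p under 0.05, where the other 6 had 95 to 606 and the real split 3304.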
